A study of Mus musculus with 21 samples.

How the data were processed

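Messenger RNA was sequenced from 21 Hepa1-6 tumours of C57BL/6 mice. Per the labels, total RNA was taken from frozen tumour tissue and libraries were made with the TruSeq Stranded mRNA kit. The mice were WT or depleted of B cells and were given isotype antibody or anti-PD1 with anti-CTLA4; how B cells were depleted is not stated in the labels. The groups were taken from the sample titles: WT isotype (5), WT combination (5), B-depleted isotype (6) and B-depleted combination (5). The stated purpose of the series is the role of B cells in the response of liver cancer to these antibodies. The labels do not state whether each library is a separate animal.

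The deposited table holds raw read counts for 55487 Ensembl gene identifiers in 21 columns, 1 per library, as the whole numbers and unequal column totals show. Per the submitters' processing notes, cutadapt 2.4, STAR 2.7.2a and the genome GRCm38 were used; the program that counted reads and the annotation release are not given in the sources used here. Identifiers were matched without their version to GENCODE M21, which gave symbols for 55227; the other 260 held 0.0183% of the counts and were kept in the fits. Of the identifiers, 15936 were at 0 in every library.

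Total counts ran from 9.52 to 19.17 M, with a median of 15.9 M. In replicate order they were 18.11, 15.03, 17.01, 17.46 and 18.13 M in WT isotype, 17.78, 15.76, 15.9, 16.86 and 15.35 M in WT combination, 15.97, 15.59, 10.92, 17.96, 16.85 and 19.17 M in B-depleted isotype, and 9.52, 12.98, 13.44, 12.31 and 14.01 M in B-depleted combination. At the lowest depth 1 CPM is about 9.52 counts, so genes under 1 CPM rest on few counts per library. No 2 columns were identical; within groups, 45 pairs of libraries correlated at r from 0.9427 to 0.988, and the lowest chi-square per degree of freedom between 2 of them was 6.99, so none were repeat runs of 1 library by this measure. The first principal component of the 2000 most variable genes held 50.7% of the variance and placed the WT combination libraries, at -20.6 or lower, toward 1 end with B-depleted combination replicate 5 (-22.8) among them. The other components held 9.8% or less.

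Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with the 4 groups (19061 genes), scaled by TMM (factors from 0.953 to 1.029) and fitted with the robust quasi-likelihood method on all 21 libraries in 1 model of 4 groups without covariates; the common biological coefficient of variation was 0.246. There were 5 tests: the combination against isotype in WT and in B-depleted tumours, B-depleted against WT under isotype and under the combination, and the interaction, which is the difference between the 2 antibody responses. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in a comparison. Levels in the text are CPM of the library total without scaling factors.

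There were 27 fixed gene lists: B cells, plasma cells and immunoglobulin constant genes, T cells, cytotoxic lymphocyte effectors, T-cell checkpoint and costimulatory receptors, regulatory T cells, lymphoid aggregate genes, interferon-gamma response, type I interferon response, MHC class I and class II presentation, macrophages, neutrophils, dendritic cells, fibroblasts and matrix, endothelium, hepatocytes, hepatoma and oncofetal genes, cell cycle, hypoxia and glycolysis, acute phase, skeletal muscle, adipocytes, epidermis, red blood cells, and 2 lists for RNA quality (mitochondrially encoded genes; handling stress and immediate early genes). Each was tested with camera at a preset correlation of 0.01, adjusted over the 27 lists of a comparison, and again with an estimated correlation between genes and with the rotation test fry. Members were counted as risen, fallen or not passing over all genes, and again with p adjusted over the list alone. A list score per library was the mean log2 CPM (prior count 2) of the tested members, compared by an exact permutation test of the group means. With 5 libraries against 5 there are 252 splits and the smallest p is 0.0079, so a single list that differed would have an adjusted p of 0.214 at best, and at least 5 lists must reach that p to pass; 5 against 6 gives 462 splits.

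The comparisons, lists, tests, naming rule and first set of alternatives were fixed before the data were examined. Genes were named by that rule: the 8 largest rises and 8 largest falls past the threshold with a mean of at least 1 CPM, leaving out predicted genes, Riken clones, pseudogenes and receptor segments, or the 5 of smallest p where none passed; up to 4 called members of each list, or 2 as values where none passed; and 20 genes in every comparison, 1 of which is not reported here and was left out of the search for values far from their arm. The antibody responses of the 2 backgrounds, which share no library, were compared by correlation over genes. WT combination libraries enter both the WT comparison and the B-depleted against WT comparison under the combination, so the overlap of those 2 was not analysed.

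The alternatives fixed beforehand were DESeq2 1.42.0 (Wald test), limma voom with sample quality weights, DESeq2 or upper-quartile scaling, no filter or a filter of 1 CPM in 5 libraries, a fit without robust estimation, only the 2 groups compared, a 2-fold threshold, other list scores, and leaving out each of the 21 libraries in turn. Chosen after the data were seen were the Y-linked level as a covariate, thinning of all libraries to the shallowest, and leaving out 3 B-depleted libraries with B-cell or immunoglobulin transcripts or 2 WT isotype libraries that stood apart on principal components 2 and 4. The sex of the mice is not given in the labels, so the Y-linked level is a marker of host RNA only by hypothesis. It was the sum of Ddx3y, Eif2s3y, Kdm5d and Uty in CPM, and slopes of each gene on its log2 were fitted within groups. Permutation of relations between genes across libraries used 100000 shuffles within groups. For the number of genes called, 100 splits of the samples were drawn with a fixed seed. Tables were handled in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plotted with matplotlib 3.10.9.

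The model was tested on simulated counts of 19061 genes with the same groups and depths. With 50 genes changed at each of 4 sizes in the WT comparison, 17, 35, 48 and 50 were recovered at 1.5-, 2-, 4- and 8-fold, with 6 false among 167 calls; for the combination comparison 15, 36, 48 and 48 (6 false of 164), and for the interaction 6, 28, 45 and 47 (7 false of 138). A comparison simulated without change gave 0 calls. A T-cell list raised 2-fold had a camera adjusted p of 3.69e-30 and 0 of 26 other lists passed. With list scores, raising 1 list by 1 log2 unit or 6 lists passed 0 of them, and raising 12 passed 11. Genes were drawn independently of each other in these simulations. They therefore do not test camera or the scores on lists whose genes vary together. The T-cell list did so in the real data, with an estimated correlation of 0.694 in the WT comparison.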

Results

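Hepa1-6 hepatoma tumours from C57BL/6 mice were compared after isotype antibody or the combination of anti-PD1 and anti-CTLA4, with B cells present (WT) or depleted. The 4 arms held 5 libraries each, except B-depleted isotype with 6. The labels do not say whether libraries come from separate animals, so p-values of genes and list scores measure the spread between samples. Camera p-values at the preset correlation compare the genes of a list with other genes. They allow little for list members that vary together between samples, which the estimated correlation allows for. Changes are log2 fold changes ± SE with edgeR adjusted p over 19061 genes, and levels are CPM as mean ± SD over the libraries of an arm.

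In WT tumours the combination raised transcripts of T cells and of their killing machinery about 4-fold. Gzmb, which encodes the granule protease granzyme B, rose from 11.6 ± 3.43 to 52.0 ± 14.6 CPM (n = 5 each; 2.18 ± 0.25, adjusted p = 1.81e-05). Perforin (Prf1) rose from 18.1 ± 5.36 to 63.3 ± 7.83 CPM, Cd8a from 26.2 ± 6.98 to 103 ± 18.2 CPM, and the effector cytokine Ifng from 1.92 ± 0.904 to 9.44 ± 1.62 CPM. All 5 combination libraries lay above all 5 isotype libraries for each of these 4 genes. Of the 22 T-cell genes, 21 rose and 1, the naive and memory cell factor Tcf7, fell (-1.17), a median of 1.93 (camera adjusted p = 1.46e-17; adjusted p = 0.213 with an estimated correlation). Of 18 cytotoxic effector genes, 17 rose, a median of 1.97 (1.39e-15; adjusted p = 0.213 with an estimated correlation), and adjusting over each list alone gave the same counts for both lists. With the summed level of 4 Y-linked genes as a covariate, a setting chosen after the data were seen, the 2 medians were 0.87 and 0.95, and Cd4 turned negative (-0.17). The targets of the 2 antibodies rose too, Pdcd1 by 1.78 ± 0.25 and Ctla4 by 1.19 ± 0.28, with Cd274, the PD-1 ligand, going from 156.8 ± 38.1 to 372 ± 27.1 CPM. In all, 12 of 15 checkpoint and costimulatory receptor genes rose, and Havcr2 (1.52) and Icos (2.10) were among them (list median 1.27, camera adjusted p = 6.22e-08; adjusted p = 0.213 with an estimated correlation).

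Antigen presentation and the genes that interferon induces rose with the T-cell transcripts. All 16 MHC class I presentation genes rose (median 0.71), and H2-K1, which encodes a class I heavy chain, went from 273 ± 74.7 to 906 ± 228 CPM (1.76 ± 0.29, adjusted p = 0.000169 by edgeR). In the interferon-gamma list 25 of 28 rose (26 over the list alone; median 0.97), among them Socs1 (1.23) and Ifi47 (1.03), and in the type I interferon list 19 of 24 rose (20 over the list alone; median 0.69). Class II presentation followed with 8 of 9 genes (median 1.37), among them H2-Aa (1.49) and Cd74 (1.20), as did 5 of 8 lymphoid aggregate genes (median 1.16), such as Il7r (1.97). Regulatory T-cell genes rose in 4 of 7 cases (median 0.92), Il2ra by 1.27, while Foxp3 (0.90 ± 0.49, adjusted p = 0.135 by edgeR) did not pass. With the Y-linked covariate the regulatory T-cell median turned to -0.35. Camera adjusted p ran from 6.03e-09 to 0.0203 over these 6 lists and from 0.427 to 0.460 with an estimated correlation.

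Macrophage, dendritic cell and stromal transcripts rose as well in the model without covariates. Macrophage genes rose in 13 of 15 cases (median 1.24), and the lipid receptor Trem2 went from 6.74 ± 2.61 to 38.3 ± 12.2 CPM (2.53 ± 0.32, adjusted p = 3.82e-05 by edgeR). Fibroblast and matrix genes rose in 14 of 20 cases (median 1.42), among them the collagen VI genes Col6a1 (1.74), Col6a2 (1.85) and Col6a3 (1.63). Endothelial genes rose in 7 of 14 (median 0.61; Eng 1.20) and dendritic cell genes in 5 of 12 (4 over the list alone; median 0.92; Clec9a 1.68). Skeletal muscle genes rose in 4 of 14 (0 over the list alone; median 1.99). B-cell genes rose in 9 of 11 cases (10 over the list alone; median 1.93), with Cd79a, part of the B-cell receptor, going from 0.374 ± 0.203 to 1.76 ± 0.866 CPM, and 1, the B-lineage factor Pax5, fell from 30.1 ± 5.84 to 14.6 ± 4.12 CPM (-1.03 ± 0.21, adjusted p = 0.000888 by edgeR). Only Ighd (2.37) rose among 10 plasma cell and immunoglobulin genes, a list that did not pass (median 1.48, camera adjusted p = 0.161). With the Y-linked covariate the medians of macrophages (-0.22), fibroblasts (-0.87), endothelium (-0.80), dendritic cells (-0.58) and B cells (-0.62) turned negative, as did Eng (-0.42), Cd79a (-0.61) and Ighd (-0.91). The 6 lists that passed had camera adjusted p from 3.94e-07 to 0.0195, and from 0.427 to 0.596 with an estimated correlation. Without WT_combo replicate 4 the adjusted p of Ighd was 0.0587; plasma cell genes passed as a list without WT_isotype replicate 1 (0.0319) or WT_combo replicate 1 (0.0229).

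Liver and proliferation transcripts moved the other way in the same tumours. Apob, a liver lipoprotein gene, fell from 547 ± 57.0 to 123 ± 77.8 CPM (-2.13 ± 0.36, adjusted p = 0.000198 by edgeR), below all isotype libraries in each of the 5 combination libraries. Of 9 hepatocyte genes 7 fell (median -2.13), including the liver regulator Hnf4a (-1.90) and Ttr (-4.00), and of 8 hepatoma and oncofetal genes 5 fell (median -1.04), with Afp going from 701 ± 560 to 97.9 ± 92.6 CPM. The arms overlapped here: Afp was at 137.8 and 171.1 CPM in WT_isotype replicates 1 and 2, against 760.4 CPM or more in the other 3, and at 251.9 CPM in WT_combo replicate 3. The hepatocyte scores of these 3 named libraries were 3.66, 3.57 and 3.64. Cell-cycle genes fell in 16 of 23 cases (18 over the list alone; median -0.52), among them the mitotic kinase Aurka (-0.77) and Cdk1 (-0.80). In the mitochondrially encoded list, read here as a marker of RNA quality, 5 of 10 fell (6 over the list alone; median -0.59; mt-Cytb -0.95). Hypoxia and glycolysis genes fell in 4 of 15 cases and Pfkfb3 rose (median -0.37, camera adjusted p = 0.0419), a call lost without WT_isotype replicate 3 (0.0744), WT_combo replicate 4 (0.101) or 5 (0.0731), or Bdep_combo replicate 5 (0.0681). The Y-linked covariate turned the cell-cycle (0.16) and hypoxia (0.20) medians positive and Pfkfb3 negative (-0.16). Camera adjusted p ran from 4.98e-05 to 0.0419 for these 5 lists and from 0.427 to 0.585 with an estimated correlation.

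Several lists did not pass in WT tumours. Neutrophil genes split, 4 rising (3 over the list alone) and Ly6g falling (-2.54), with a median of -0.31, a mean of 0.10 and a test direction of up (camera adjusted p = 0.831). Acute phase genes (median -0.60, with Fga at -6.34), adipocyte genes (0.22), epidermal genes (-0.07, with Krt5 at -2.58), red blood cell genes (0.37) and the handling stress list (-0.33) had camera adjusted p from 0.707 to 0.831. Within the last, Egr2 (1.33) and Jun (0.60) rose and 3 genes fell, among them Egr1 (-0.82). Across all genes 9529 were called, 4766 higher and 4763 lower, of which 3390 changed at least 2-fold. With the Y-linked covariate 77 were called, 43 of them shared, and 3139 of the 9529 took the opposite sign. By list scores, the mean log2 CPM of a list per library, 15 of 27 lists passed in an exact permutation test over 252 splits, T cells by 1.85 and cytotoxic effectors by 1.98 (adjusted p = 0.0195 for both).

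**Figure D1:**
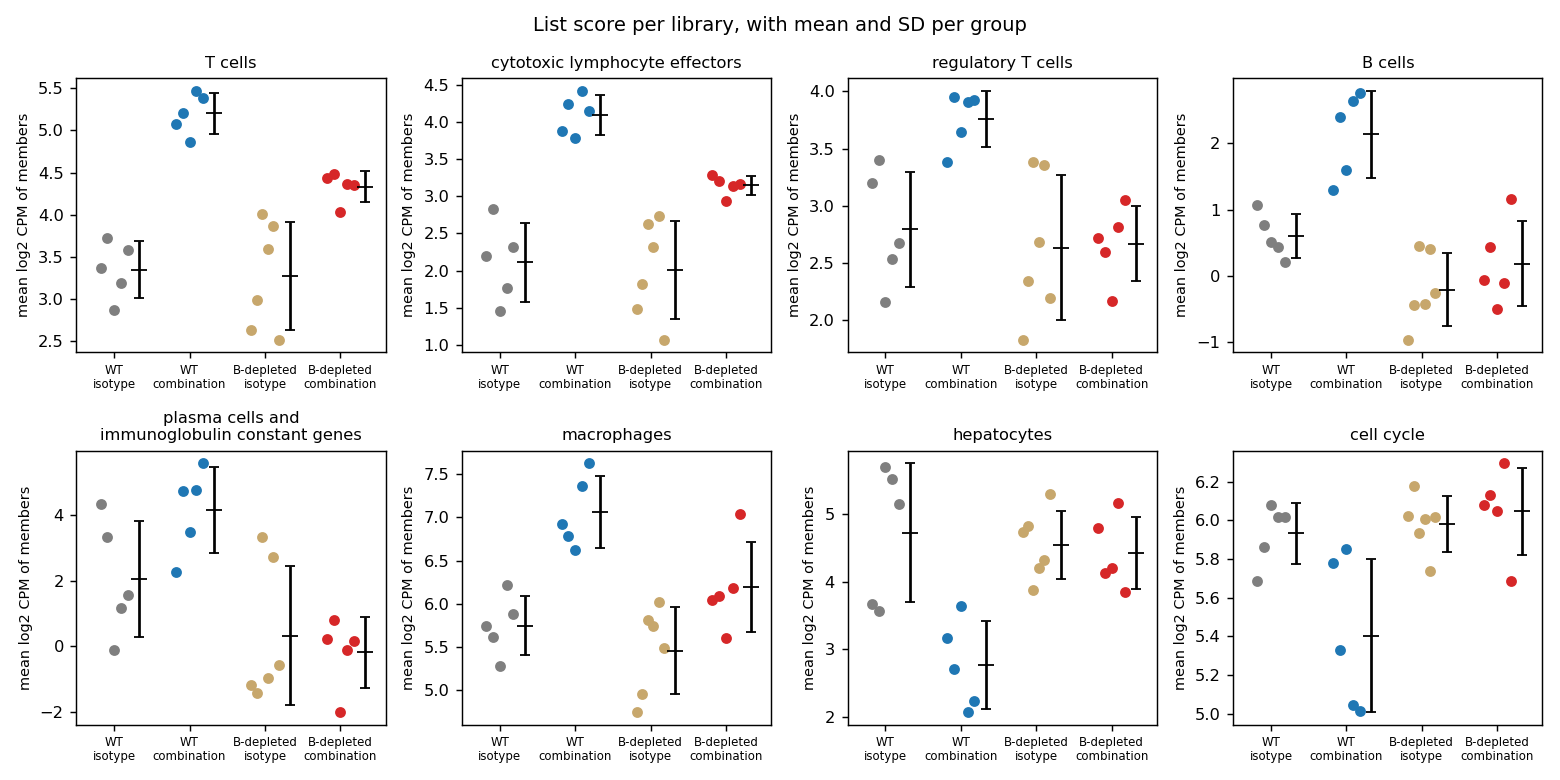
Scores of 8 gene lists in each library (points), with the mean and SD of each arm. A score is the mean log2 CPM of the tested members of a list.

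In B-depleted tumours the combination again raised T-cell and cytotoxic transcripts, by about 2-fold. Prf1 went from 15.2 ± 5.08 to 45.9 ± 5.66 CPM (n = 6 and 5; 1.62 ± 0.19, adjusted p = 0.00117 by edgeR) and Gzmb from 10.7 ± 3.87 to 26.8 ± 3.50 CPM (1.35 ± 0.23, adjusted p = 0.0137). Cd8a rose from 25.3 ± 11.1 to 68.5 ± 5.20 CPM, and Pdcd1 from 9.64 ± 4.90 to 24.5 ± 2.82 CPM. All 5 combination libraries lay above all 6 isotype libraries for these 4 genes. Of 18 cytotoxic effector genes 8 rose (13 over the list alone; median 1.20, camera adjusted p = 8.76e-29; adjusted p = 0.0563 with an estimated correlation). Of 22 T-cell genes 6 rose (18 over the list alone, where Tcf7 fell; median 1.05, 7.29e-30; adjusted p = 0.0563 with an estimated correlation). The list scores of both lists, 1.06 for T cells and 1.14 for cytotoxic effectors, had exact permutation adjusted p = 0.0779 over 462 splits, and 0 of 27 lists passed. Without Bdep_isotype replicate 2 the edgeR adjusted p of Gzmb and of Pdcd1 was 0.0538; Prf1 and Cd8a kept their calls in every refit without 1 library.

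Other immune lists had medians of 0.75 or lower in these tumours, and whether they moved less than the T-cell list was not tested. The interferon-gamma list had a median of 0.42 (camera adjusted p = 3.87e-12; adjusted p = 0.393 with an estimated correlation) with 0 of 28 genes called (1 over the list alone), MHC class I presentation 0.37 (1.38e-07; adjusted p = 0.393 with an estimated correlation) with 0 of 16, and macrophages 0.75 (9.65e-11; adjusted p = 0.254 with an estimated correlation) with Trem2 (1.41, adjusted p = 0.0422 by edgeR) as the 1 gene called (11 over the list alone). Checkpoint receptor genes passed with a median of 0.44 (3.81e-08; adjusted p = 0.0891 with an estimated correlation), Pdcd1 and Havcr2 (0.96) being called. Class II presentation (0.38, 0.0354), fibroblasts (0.68, 0.000175), hypoxia (-0.26, 0.000795) and skeletal muscle (-2.23, 4.99e-05) also passed, with adjusted p from 0.597 to 0.745 with an estimated correlation. Ctla4 was at 7.57 ± 3.01 and 7.87 ± 3.00 CPM (0.10 ± 0.27, adjusted p = 0.896), the regulatory T-cell list had a median of 0.01, a mean of -0.04 and a test direction of down (camera adjusted p = 0.986), and hepatocyte (-0.29, 0.538; mean 0.27), cell-cycle (0.07, 0.506), B-cell (0.45, 0.107) and adipocyte genes (2.67, 0.0769) did not pass. The Y-linked covariate turned the fibroblast median to -0.19 and the test direction of class II presentation (median 0.078). Class II presentation lost its call without Bdep_isotype replicate 1 (0.112) or 6 (0.192) or Bdep_combo replicate 1 (0.0631) or 2 (0.0644), and fibroblasts without Bdep_combo replicate 5 (0.162). B-cell genes passed without Bdep_isotype replicate 5 (0.042) or Bdep_combo replicate 1 (0.036) or 3 (0.0251), cell-cycle genes without Bdep_combo replicate 5 (0.00553), and adipocyte genes without Bdep_combo replicate 1 (0.0177), 2 (0.0137), 3 (0.0251) or 5 (0.0113). Trem2 kept its call in 8 of 21 refits, losing it without WT_isotype replicate 1 (0.0508), 2 (0.0531) or 5 (0.059), WT_combo replicate 2 (0.0581) or 5 (0.0529), Bdep_isotype replicate 1 (0.131), 2 (0.124), 4 (0.0586) or 6 (0.106), or Bdep_combo replicate 1 (0.0906), 2 (0.0688), 3 (0.0604) or 5 (0.138). Havcr2 lost it without Bdep_isotype replicate 1 (0.0509) or 2 (0.0541) or Bdep_combo replicate 5 (0.0532).

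Across all genes 65 were called in B-depleted tumours, 58 higher and 7 lower. The count rose to 392 by DESeq2, 300 by limma voom and 397 without 3 B-depleted libraries that held B-cell or immunoglobulin transcripts. It fell to 6 with only the 2 groups compared, 31 with the Y-linked covariate, 35 without a filter, 43 with all libraries thinned to the shallowest, 40 without the 2 WT isotype libraries that stood apart, and 33 and 14 with a block by title number and by description code. The lipid desaturase gene Fads2 (-0.68) was among the falls called. Of the 65, 63 were also called in WT tumours with the same sign, and 47 of them had the larger change there. Leaving out 1 library gave 11 to 176 genes, the count moving by more than 1.5 times without WT_isotype replicate 1 (43) or 5 (36), WT_combo replicate 2 (40), Bdep_isotype replicate 1 (17), 2 (11), 3 (176), 4 (43), 5 (163) or 6 (27), or Bdep_combo replicate 1 (30), 3 (38) or 5 (18). Fads2 lost its call without Bdep_isotype replicate 1 (adjusted p = 0.057), 2 (0.0822) or 4 (0.0531) or Bdep_combo replicate 1 (0.0551) or 5 (0.0883). The signal recognition particle RNA Rn7s2 (4.90, adjusted p = 0.0228) was at 181 and 164 CPM in replicates 3 and 4 of the combination arm, and lost its call without Bdep_isotype replicate 1 (0.0743), 2 (0.0804), 4 (0.0539) or 6 (0.07) or Bdep_combo replicate 3 (0.0567).

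The response itself differed between the arms in 5 genes, and the direction of change was shared by most of the genes called in either arm. Over 19061 genes the 2 sets of log2 fold changes, which share no library, correlated at Pearson r = 0.54 (jackknife SE 0.264; 0.147 without a filter on low counts and 0.336 without Bdep_combo replicate 5) and Spearman rho = 0.65; genes are not independent replicates. Among the 9531 genes called in either, 87.9% had the same sign, a share over genes called mostly for their change in WT tumours. The median size of the 9529 WT changes was 0.72, and the median of the same genes in B-depleted tumours, taken in the WT direction, was 0.20. Hopx, a transcription cofactor gene expressed in lymphocytes among other cells, went from 3.97 ± 0.497 to 10.5 ± 1.88 CPM in WT tumours and from 5.70 ± 0.818 to 5.86 ± 0.834 CPM in B-depleted ones (difference -1.36 ± 0.20, adjusted p = 0.0241 by edgeR). Atp6v0d2, which encodes a proton pump subunit, rose in both arms, to 95.4 ± 24.5 and 39.4 ± 3.95 CPM (difference -1.25, adjusted p = 0.0484). Oxct2b (2.33) and Srrm4 (1.47), both at adjusted p = 0.0345 by edgeR, fell in WT tumours, from 2.05 ± 0.262 to 0.394 ± 0.117 CPM and from 11.7 ± 1.15 to 5.01 ± 1.74 CPM. In B-depleted tumours they went from 2.01 ± 0.758 to 1.98 ± 0.565 CPM and from 8.29 ± 1.30 to 9.87 ± 1.27 CPM. For Srrm4, 5 of the 6 B-depleted isotype libraries lay below all WT isotype libraries, and for Hopx 5 of the 6 lay above all of them. Part of the difference of Srrm4 and of Hopx thus lies between the isotype arms. The fifth, Gm49146 (ENSMUSG00000114544.1, 5.26, adjusted p = 0.0345), lies outside the naming rule and was picked after its value was seen. It went from 1.042 ± 0.5775 to 0.04632 ± 0.07364 CPM in WT tumours, with 0 CPM in WT_combo replicates 2, 4 and 5. In B-depleted tumours it went from 0.392 ± 0.1115 to 0.8232 ± 0.294 CPM. The size of its difference thus rests on few counts. Hopx kept its call in 15 of 21 refits without 1 library, losing it without WT_isotype replicate 2 (0.058), 4 (0.0605) or 5 (0.0829), Bdep_isotype replicate 2 (0.0504) or 5 (0.0533), or Bdep_combo replicate 4 (0.06). Oxct2b, Srrm4 and Atp6v0d2 kept theirs in 7 of 21 refits each, with highest adjusted p of 0.0999, 0.12 and 0.132. All 3 kept it without WT_isotype replicate 1, WT_combo replicate 1 or 3 and Bdep_combo replicate 5, and Oxct2b and Srrm4 without Bdep_isotype replicate 1 and Bdep_combo replicate 3. Calls were also kept by Oxct2b and Atp6v0d2 without Bdep_isotype replicate 6, Srrm4 and Atp6v0d2 without Bdep_isotype replicate 4, and Atp6v0d2 without WT_combo replicate 2.

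Gene by gene, no member of the 27 lists differed in response between the arms past the threshold. Over each list alone, 17 of 23 cell-cycle, 7 of 9 hepatocyte, 4 of 8 hepatoma and 4 of 10 mitochondrially encoded genes passed with a difference in response above 0, B-depleted minus WT. By the same measure 12 of 14 skeletal muscle, 9 of 15 checkpoint receptor (with 1 above 0), 7 of 16 MHC class I, 5 of 22 T-cell, 5 of 12 dendritic cell, 2 of 7 regulatory T-cell, 2 of 8 lymphoid aggregate, 2 of 24 type I interferon and 1 of 10 plasma cell genes passed with a difference below 0, and 0 cytotoxic effector genes passed. Gzmb (-0.83, adjusted p = 0.140 by edgeR), Ctla4 (-1.10, 0.117), H2-K1 (-1.02, 0.130), Cd4 (-1.72, 0.133) and Foxp3 (-1.42, 0.207) had negative differences, Prf1 (-0.21, 0.632) and Cd8a (-0.53, 0.327) smaller ones. As lists, T cells (median -0.84, camera adjusted p = 3.06e-07), cytotoxic effectors (-0.96, 1.03e-05), type I interferon (-0.63, 5.53e-07), MHC class I (-0.45, 4.98e-06), checkpoint receptors (-0.72, 5.74e-05) and regulatory T cells (-1.22, 0.0019) were lower, and cell cycle (0.57, 6.88e-09) and hepatocytes (2.85, 2.07e-05) higher. In all 20 of 27 lists passed at the preset correlation, 16 lower and 4 higher; the lowest adjusted p = 0.327 with an estimated correlation, and the rotation test fry passed 0 lists. The count of 5 genes (4881 at an unadjusted p under 0.05; 1154 by DESeq2 and 4131 by limma voom) was 0 with the Y-linked covariate, thinned or with a block by title number, 1 without the 3 B-depleted libraries and 2007 without the 2 WT isotype libraries that stood apart. It ranged from 0 to 1540 when 1 library was left out. It was 0 without WT_isotype replicate 2, 4 or 5, Bdep_isotype replicate 2 or 5, or Bdep_combo replicate 4, and 1 without WT_combo replicate 4 or 5, Bdep_isotype replicate 3 or Bdep_combo replicate 2. The value was 2 without WT_isotype replicate 3 or WT_combo replicate 2; 3 without Bdep_combo replicate 1; 8 without Bdep_isotype replicate 1; 361 and 1540 without WT_combo replicate 1 and 3; and 1382 without Bdep_combo replicate 5.

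**Figure D2:**
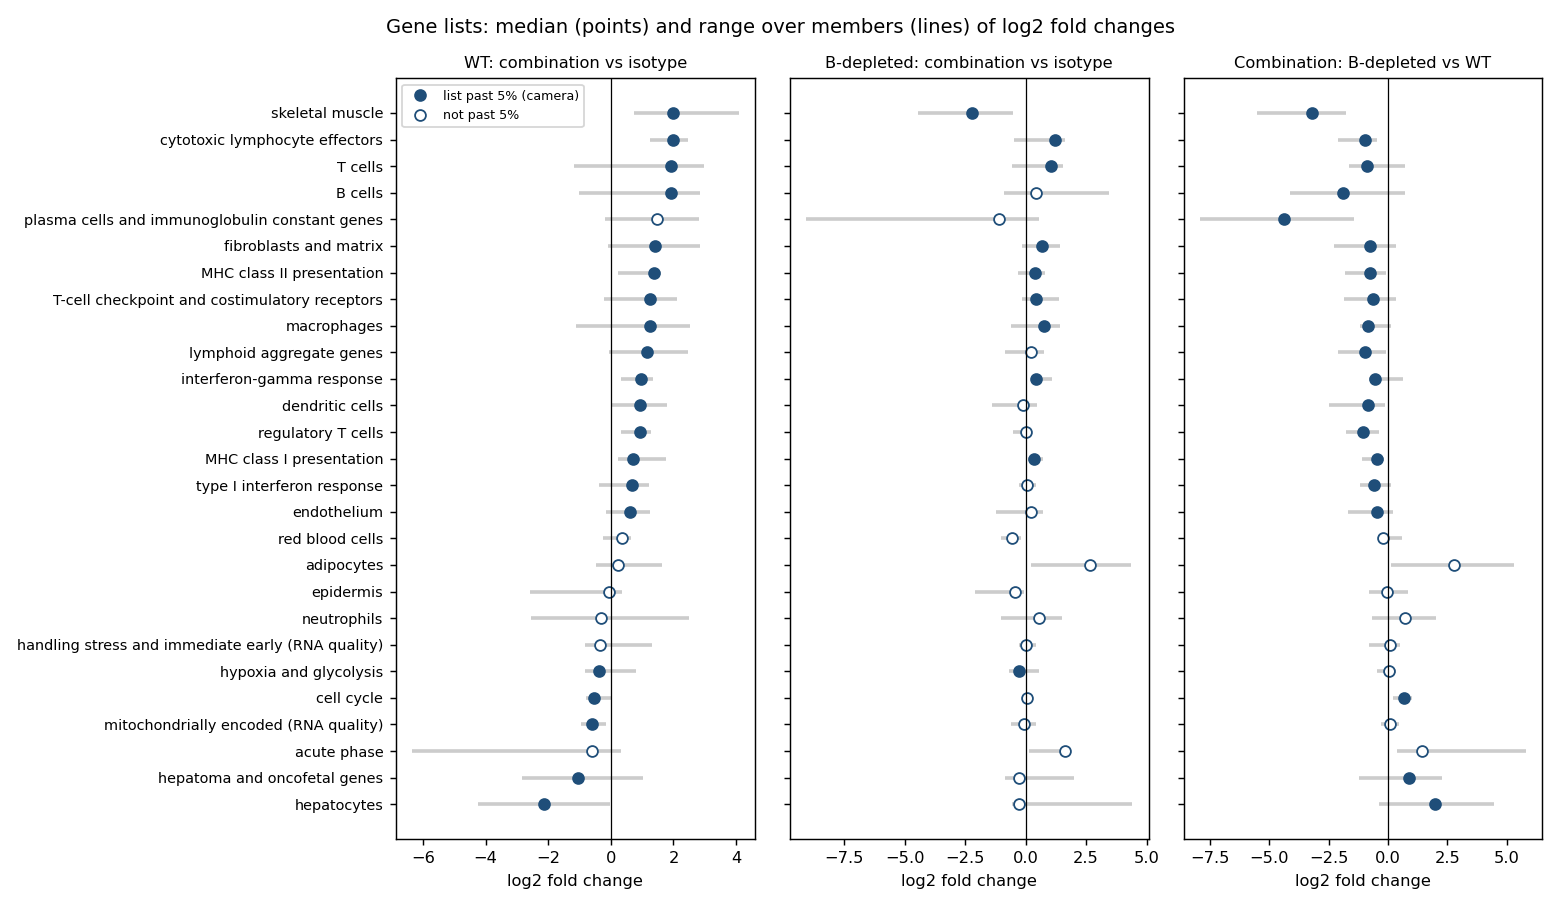
Median log2 fold change of 27 gene lists, with the range of their members, in the 2 antibody comparisons and in B-depleted against WT tumours under the combination. Filled points passed camera at an adjusted p of 0.05 with the preset correlation.

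Under the combination, B-depleted tumours held less B-cell and immunoglobulin transcript than WT tumours. Cd79a was at 1.76 ± 0.866 CPM in WT and 0.0857 ± 0.192 CPM in B-depleted tumours (n = 5 each; -4.11 ± 0.82, adjusted p = 0.0055 by edgeR). Ighg2b fell from 48.4 ± 40.8 to 0.201 ± 0.206 CPM (-7.92 ± 1.40, adjusted p = 0.00458), and Ighm from 57.7 ± 28.4 to 8.50 ± 4.34 CPM. Of 11 B-cell genes 8 fell (10 over the list alone; median -1.89, camera adjusted p = 2.66e-05) and Pax5 rose (0.71 ± 0.21, adjusted p = 0.0214 by edgeR). Of 10 plasma cell and immunoglobulin genes 8 fell (10 over the list alone; median -4.39, 1.70e-05); both lists had adjusted p = 0.310 with an estimated correlation. Iglc1 was at 5.13 ± 2.91 CPM in WT tumours and at 1 count over the 5 B-depleted libraries. Single libraries overlapped for Ms4a1, at 1.571 CPM in Bdep_combo replicate 5 against 1.35 and 0.9435 CPM in WT_combo replicates 1 and 3. The B-cell score of that B-depleted library, 1.161, was above all 5 WT isotype libraries. The list scores separated the 2 arms completely for both lists (-1.95 and -4.36, exact permutation adjusted p = 0.0165).

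T-cell transcripts, those of regulatory cells included, were lower in these tumours, and proliferation and liver genes higher. Ctla4 (-1.27 ± 0.28, adjusted p = 0.00803 by edgeR), Il2ra (-1.41), Foxp3 (-1.77) and Gzmb (-0.96) fell, the last from 52.0 ± 14.6 to 26.8 ± 3.50 CPM, whereas Cd8a (-0.59, adjusted p = 0.0694), Prf1 (-0.48, 0.0709) and Pdcd1 (-0.54, 0.0937) did not pass. Of 22 T-cell genes 19 fell (21 over the list alone) and Tcf7 rose (median -0.90, camera adjusted p = 4.84e-08); of 18 cytotoxic effector genes 12 fell (17 over the list alone; median -0.96), and of 7 regulatory T-cell genes 5 fell (median -1.04). Type I interferon genes fell in 15 of 24 cases (19 over the list alone; median -0.60; Ifit1 -1.06), MHC class I genes in 8 of 16 (12 over the list alone; median -0.46; B2m -0.51), macrophage genes in 11 of 15 (13 over the list alone; median -0.85; Cd68 -0.90) and interferon-gamma genes in 6 of 28 (11 over the list alone; median -0.55). Checkpoint receptor (9 of 15, 11 over the list alone, -0.65), lymphoid aggregate (3 of 8, 4 over the list alone, -0.98), class II (6 of 9, -0.78), dendritic cell (7 of 12, -0.83), fibroblast (5 of 20, -0.76), endothelial (3 of 14, 2 over the list alone, -0.47) and skeletal muscle genes (8 of 14, 13 over the list alone, -3.20) also fell as lists. Cell-cycle genes rose in 20 of 23 cases (21 over the list alone; median 0.68; Aurka 1.00 ± 0.18), hepatocyte genes in 7 of 9 (8 over the list alone) with Ass1 falling (median 1.99; Apob 1.39), and hepatoma genes in 5 of 8 (median 0.90, with 1 falling over the list alone; Afp 2.25). The Y-linked covariate turned the fibroblast (0.35) and endothelial (0.25) medians positive. Camera adjusted p ran from 2.31e-11 to 0.0274 over these 17 lists and from 0.310 to 0.488 with an estimated correlation. Hepatoma genes lost their call without WT_combo replicate 2 (0.0553) and endothelial genes without WT_combo replicate 5 (0.051); Afp lost its call without WT_combo replicate 4 (0.0548) or 5 (0.0508).

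Across all genes 5545 differed under the combination, 2963 higher and 2582 lower in B-depleted tumours, and 4 with the Y-linked covariate. By limma voom 8859 were called, without a filter 3343 and with only the 2 groups compared 3727. The count was 2182 and 2251 without WT_combo replicate 4 and 5, and 3635, 3042 and 3336 without Bdep_combo replicate 1, 3 and 4. The fat and liver genes Cfd (5.28) and Cyp2e1 (4.44) rested on Bdep_combo replicate 4, at 138 and 51.1 CPM; without it they were at -0.76 and -0.93. Both also lost their calls without WT_combo replicate 2 (0.0569 and 0.0549) or 4 (0.0733 and 0.0662), and Cfd without WT_combo replicate 5 (0.0528). The hair follicle gene Tchh (-4.30) rested in the same way on WT_combo replicate 2, at 97.8 CPM; without it the value was -0.52.

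Without checkpoint antibodies, B-depleted and WT tumours differed in 0 genes by edgeR. DESeq2 called 5 and limma voom 1, and edgeR called 16 with the Y-linked covariate, 25 without the 2 WT isotype libraries that stood apart, and 1 without a filter or with a block by either number. In all 563 genes had an unadjusted edgeR p under 0.05. The smallest adjusted p belonged to Klf15, a metabolic transcription factor gene, at 2.78 ± 2.24 CPM in WT and 0.443 ± 0.129 CPM in B-depleted tumours (-2.65 ± 0.42, adjusted p = 0.0583 by edgeR). The B-cell surface gene Ms4a1 was at 0.464 ± 0.351 CPM in WT tumours (n = 5) and 3 counts over the 6 B-depleted libraries, and did not pass (adjusted p = 1.00). All 6 B-depleted libraries lay below all 5 WT libraries for this gene. As lists, B-cell genes (median -0.68, camera adjusted p = 6.22e-08; adjusted p = 0.1252 with an estimated correlation) and plasma cell genes (-1.25, 7.48e-07; adjusted p = 0.346 with an estimated correlation) were lower. T-cell genes (median -0.03, mean 0.01, 0.70) and cytotoxic effector genes (-0.06, 0.52) did not pass; leaving out WT_isotype replicate 3 (0.0205 and 0.00899), Bdep_isotype replicate 3 (0.00168 and 0.00982) or Bdep_isotype replicate 5 (0.0295 and 0.0146) brought both past the threshold. Mitochondrially encoded genes, the RNA quality list, had a median of -0.46 (camera adjusted p = 2.89e-15, and 0.0288 with an estimated correlation). Over the list alone 7 of 10 were lower, among them mt-Co3 (-1.21), at 2.36 ± 0.790 CPM in WT and 1.04 ± 0.249 CPM in B-depleted tumours. By list score the difference was -0.42 with exact permutation adjusted p = 0.234. All mitochondrial transcripts made up 2.12 to 2.61% of counts in WT and 1.94 to 2.15% in B-depleted isotype libraries.

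Macrophage (median -0.21, camera adjusted p = 0.00141), hepatocyte (-0.61, 0.0137), skeletal muscle (1.00, 0.00042) and red blood cell genes (0.84, 0.00377) also passed in isotype tumours, with adjusted p from 0.442 to 0.804 with an estimated correlation. Macrophage genes lost the call without WT_isotype replicate 4 (0.0908) or Bdep_isotype replicate 1 (0.0801), and red blood cell genes without WT_isotype replicate 2 (0.0898) or Bdep_isotype replicate 1 (0.0753). Skeletal muscle genes lost it without WT_isotype replicate 2 (0.0562) or Bdep_isotype replicate 3 (0.304), and hepatocyte genes without WT_isotype replicate 3 (0.265), 4 (0.176) or 5 (0.0646) or Bdep_isotype replicate 3 (0.122) or 4 (0.0564). The count of genes was 2 without WT_isotype replicate 1 and 1 without WT_isotype replicate 2, and list scores passed for 0 of 27 lists in this comparison.

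Xist fell under the combination in both backgrounds, and a sum of Y-linked genes rose in WT tumours. This sum, of Ddx3y, Eif2s3y, Kdm5d and Uty, went from 71.8 ± 13.6 to 199 ± 52.8 CPM in WT tumours (log2 difference 1.45, exact permutation adjusted p = 0.0289 over 8 tests). In B-depleted tumours it went from 81.4 ± 28.3 to 113 ± 32.2 CPM and did not pass (0.51, exact permutation adjusted p = 0.177). Xist, the RNA that coats the inactive X chromosome, went from 2996 ± 188 to 1537 ± 703 CPM (-1.10, 0.0289) and from 3337 ± 474 to 2332 ± 754 CPM (-0.59, 0.0289). Under the combination the Y-linked sum was lower in B-depleted than in WT tumours (-0.81, exact permutation adjusted p = 0.0476), in the direction of the T-cell and macrophage lists, while Xist (0.66, 0.210) did not differ by this test. In isotype tumours the Y-linked sum (0.13, 0.613) and Xist (0.15, 0.210) did not differ by this test.

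**Figure D3:**
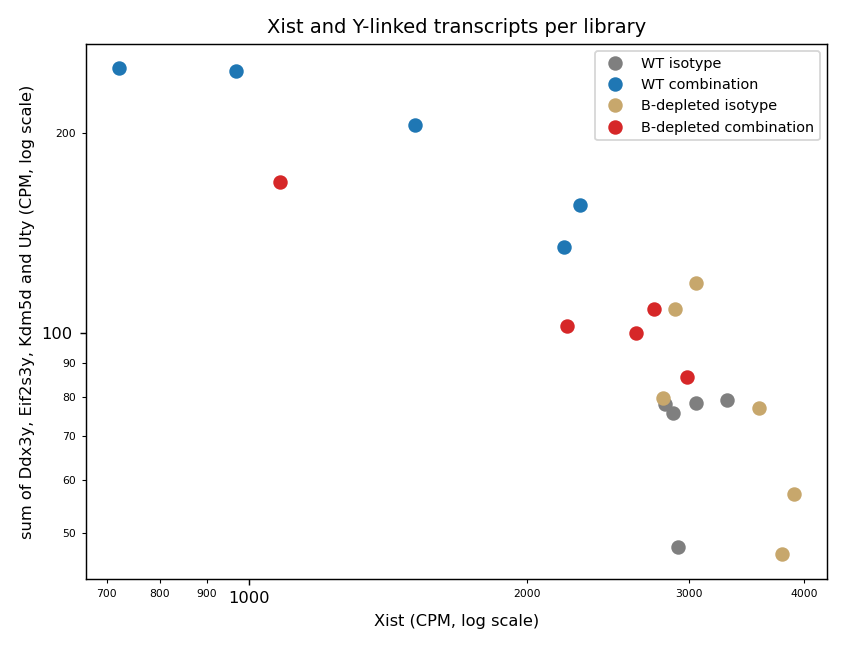
Xist against the sum of 4 Y-linked genes in each library, in CPM on log axes, coloured by arm.

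Genes named above lie on GRCm38 at chromosome 14, 56258838 to 56262260 (Gzmb, ENSMUSG00000015437.5), chromosome 10, 61297833 to 61304680 (Prf1, ENSMUSG00000037202.6), chromosome 4, 44524757 to 44710487 (Pax5, ENSMUSG00000014030.15), chromosome 5, 77086988 to 77115121 (Hopx, ENSMUSG00000059325.14), and chromosome 6, 90462576 to 90475238 (Klf15, ENSMUSG00000030087.11).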

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

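Apart from the splits of the samples, the tests of explanations in this part were chosen after the results were seen. A value was listed here when it lay far from the other libraries of its arm (Dixon's test on 37 genes, 27 list scores and depth), or when the antibody response differed between the 2 backgrounds. Of 260 arms tested, 32 held a value far from the others, 22 of them in CPM. About 1 in 20, or 13, would do so by chance if values were normally distributed. CPM were tested without logs, and the genes include some named for their large changes, so the excess over 13 is not read as a result.

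Far more genes were called for the combination in WT tumours (9529) than in B-depleted tumours (65). Lower depth of the B-depleted combination libraries did not account for this: with every library thinned to the shallowest, the ratio of the 2 counts was 202.4. Without the 3 B-depleted libraries with immunoglobulin or B-cell transcripts the ratio was 25.1 (9951 and 397 genes), against 146.6 with all libraries. These libraries may thus account for part of the gap, but not for all of it. They also held the highest Y-linked levels of their arms (108.8 and 118.9 CPM under isotype, 168.8 CPM under the combination). Their immunoglobulin or B-cell transcripts therefore cannot be told apart from that level as the reason. A larger share of host RNA in the WT combination tumours may contribute. Changes predicted from each gene's slope on the Y-linked level within groups correlated with the observed WT changes at r = 0.77 over 19057 genes. The same correlation was 0.41 for the B-depleted comparison and 0.74 for B-depleted against WT under the combination. Xist and the Y-linked level ran opposite within groups (r = -0.69), as a mixture of host RNA with Y-linked transcripts and tumour RNA with Xist would give. The sex of the mice is not given in the labels, so this reading of the Y-linked level is a hypothesis. With that level as a covariate the ratio was 2.5 (77 and 31 genes), against 146.6 without it, but the level differs between the WT arms, so the covariate also takes up part of any effect of the antibodies. The Y-linked level would rise with immune infiltration itself, so this does not part a technical from a biological cause. An effect of B-cell depletion on the response stays open: the interaction test called 5 genes, and 0 with the covariate, and does not part such an effect from a difference in host share.

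T-cell and cytotoxic genes, higher under the combination in both backgrounds, stayed higher with the Y-linked level as a covariate. Their 4 medians were at 0.77 or more (0.87 and 0.95 in WT, 0.77 and 0.88 in B-depleted tumours). All 4 passed camera at the preset correlation (adjusted p = 5.95e-14, 4.80e-13, 9.32e-27 and 3.13e-24). None of the 4 passed with an estimated correlation (adjusted p = 0.179, 0.169, 0.0603 and 0.0603). By list score with the covariate the differences were 0.78 ± 0.30, 0.90 ± 0.38, 0.69 ± 0.19 and 0.76 ± 0.24 (estimate ± SE by least squares), with 95% intervals from 0.15, 0.10, 0.28 and 0.25 upward. Without the covariate the medians were 1.93, 1.97, 1.05 and 1.20. By the bound chosen afterwards these values argue against a larger host share as the only cause. They do not exclude it, since a covariate that marks host RNA imprecisely leaves part of its effect behind. A larger share of host-derived RNA alone would also raise host cell types alike. In WT tumours 15 of the 91 pairs of 14 host cell type lists moved apart by more than their SD (exact permutation p adjusted over all pairs 0.0481 for each). Most of these pairs involved endothelium or epidermis, a list of 4 tested genes. The T-cell score rose over the dendritic cell score by 0.92 (1.03 ± 0.24 against 0.11 ± 0.34), while its rise over the neutrophil score, 1.77, had an adjusted p of 0.149. List members that tumour cells also express would rise less, which was not examined. The pairs thus argue against a larger host share alone without excluding it. The relation of Xist and the Y-linked level held over 21 libraries with a permutation p of 0.00032 (0.00096 adjusted over 3 relations; Spearman rho -0.73, p = 0.00057; r = -0.62 without the 2 farthest libraries).

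In the WT comparison 1 of 100 splits of the samples, the real one, gave as many genes (9529, highest other 7078). In B-depleted tumours 2 splits did (65, highest other 87), and in the combination comparison 2 (5545, highest other 7926). By the bound fixed beforehand, fewer than 5 of 100, this argues against chance in these comparisons. It does not exclude it where another split exceeded the real one. For the interaction 2 splits gave as many (5, highest other 4797). Those splits exchanged WT and B-depleted labels within each antibody, so they stand for no effect of depletion at all, not for equal responses. They cannot decide whether chance gave the 5 genes. For the isotype comparison the splits say nothing about chance, since with a real count of 0 all 100 must give as many (highest other 1198). The splits with 7078 and 7926 genes exchanged 1 library of each arm. The contrast they kept does not alone account for these counts. Splits that exchanged 1 library called a median of 0 genes, over 21 splits in WT tumours and 19 under the combination. The split with 87 genes exchanged 5, near the mirror of the real split. That with 1198 genes exchanged 2, where the real count was 0. That with 4797 exchanged 2 under isotype and 1 under the combination, where the real count was 5. Except for the split with 87 genes, these point to a structure of the samples.

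Immunoglobulin transcripts were high in 2 libraries of the B-depleted isotype arm. In replicate 3 Igkc was at 77.49 CPM, far from the other libraries of its arm, and Ighg2c at 52.1 CPM. For its Iglc1 reads, carry-over from another library is argued against, though only by a bound chosen afterwards. The highest Iglc1 level of another library was 7.674 times that of replicate 3, so a trace of that library would not suffice. That library, replicate 5, held Ighg2c at 0.178 CPM. The bound did not cover Igkc, the transcript flagged, which reached 503.9 CPM in another library. The highest Spearman rho of the V segments of replicate 3 with another library was 0.35. In replicate 5 Iglc1 was at 68.89 CPM, where no other library exceeded 8.98, and 46.9% of its 1803 V segment counts were Ighv9-3; the highest Spearman rho of its V segments with another library was 0.45. In replicate 3 the largest V segment, Ighv1-82, held 15.8% of 1136 counts, at 16.4 CPM against up to 78.9 CPM in another library. Antibody-producing cells left after depletion, the biological explanation, were not tested.

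Pax5 was above 10 CPM in every library while Ms4a1 was under 6 CPM. A source in B cells is argued against by its relation to Cd79b within groups (r = -0.54 over 21 libraries, permutation p = 0.033; Spearman rho -0.60, p = 0.0148; r = -0.65 without the 2 farthest). Reads from the grafted tumour cells are a candidate explanation: Pax5 rose with Xist within groups (r = 0.58, permutation p = 0.0105, 0.0157 adjusted over 3 relations; Spearman rho 0.61, p = 0.00854; r = 0.52 without the 2 farthest).

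Among list scores, values far from their arm were T cells in Bdep_combo replicate 3 (4.03), interferon-gamma response in WT_combo replicate 5 (7.28) and Bdep_isotype replicate 6 (5.18), type I interferon response in Bdep_isotype replicate 6 (3.71), neutrophils in WT_combo replicate 5 (4.92) and Bdep_combo replicate 5 (6.26), fibroblasts in WT_isotype replicate 3 (6.24), acute phase in WT_combo replicate 5 (4.53), adipocytes in Bdep_combo replicate 4 (6.13) and handling stress in WT_isotype replicate 1 (5.48). In CPM, Bdep_combo replicate 5 stood out with Ms4a1 (1.57), Cd79a (0.428) and Iglc1 (0.0714), and Bdep_combo replicate 4 with Cfd (137.9), Cyp2e1 (51.1), Klf15 (2.36) and Cxcl13 (4.55). For Cd79a and Iglc1 all other libraries of that arm were at 0 CPM, so any read in replicate 5 would have been flagged. WT_isotype replicate 1 stood out with Iglc1 (3.48), Ighg2b (39.7), Cfd (3.70) and Cyp2e1 (1.55), Bdep_isotype replicate 6 with Cxcl13 (11.1), Cfd (4.90) and Cyp2e1 (1.46), and WT_combo replicate 5 with Cxcl13 (25.3) and Cyp2e1 (1.43). Single values were Armc5 in WT_isotype replicate 3 (12180) and Bdep_isotype replicate 5 (79.3), Tchh in WT_combo replicate 2 (97.8) and Srrm4 in Bdep_isotype replicate 4 (10.9). Of these libraries, Bdep_combo replicate 4, Bdep_isotype replicate 6, WT_combo replicate 5 and WT_isotype replicate 1 held 5 such values each, with Bdep_combo replicate 5 at 4.

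The antibody response differed between backgrounds by the interaction test in Oxct2b (2.33), Srrm4 (1.47), Gm49146 (5.26, on few counts), Hopx (-1.36) and Atp6v0d2 (-1.25). By camera with the preset correlation it was lower in B-depleted tumours for B cells (median -1.22), plasma cells (-2.55), T cells (-0.84), cytotoxic effectors (-0.96), checkpoint receptors (-0.72), regulatory T cells (-1.22), lymphoid aggregate genes (-0.96), interferon-gamma (-0.55), type I interferon (-0.63), MHC class I (-0.45) and class II (-0.81), macrophages (-0.51), dendritic cells (-0.95), fibroblasts (-0.64), endothelium (-0.46) and skeletal muscle (-4.12). It was higher for hepatocytes (2.85), hepatoma genes (0.88), cell cycle (0.57) and mitochondrially encoded genes (0.51). None of the 20 lists passed with an estimated correlation (lowest adjusted p = 0.327), and the Y-linked covariate turned the medians of B cells (0.32), plasma cells (0.32), macrophages (0.43), fibroblasts (0.64) and endothelium (0.34) positive. The B-cell list lost its call without WT_combo replicate 4 (0.0737) or 5 (0.0719), Bdep_isotype replicate 3 (0.0571), 5 (0.0519) or 6 (0.0553) or Bdep_combo replicate 3 (0.0617), and endothelium without Bdep_isotype replicate 6 (0.0515).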

How the results depend on the processing

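The Y-linked covariate, thinning, and leaving out 3 B-depleted or 2 WT isotype libraries were chosen after the data were seen; the others were fixed beforehand. Under every alternative fixed beforehand 229 of 231 called results for named genes kept their direction and 148 kept direction and call. All 76 called list results kept their direction under theirs. With the Y-linked covariate 19 of the 231 kept direction and call, 193 lost the call and 19 reversed. Of the 76 list results 41 kept direction and call, 18 lost the call and 17 reversed. Where no reason is given, the cause was not tested.

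In WT tumours 3390 of 9529 genes passed a 2-fold threshold, fewer by construction, and 77 with the Y-linked covariate, 43 of them shared, 3139 of the 9529 taking the opposite sign. In B-depleted tumours (65) the counts were 35 without a filter, where more genes are adjusted for, 31 with the covariate, 43 thinned, 397 without the 3 B-depleted libraries (63 of the 65 shared), 40 without the 2 WT isotype libraries, 6 with only the 2 groups, 300 by voom and 392 by DESeq2. In the isotype comparison (0) they were 1 without a filter, 16 with the covariate, 25 without the 2 WT isotype libraries, 1 by voom and 5 by DESeq2. Under the combination (5545) they were 1244 at 2-fold, 3343 without a filter, 4 with the covariate and 8859 by voom. The interaction (5) gave 0 with the covariate, 0 thinned, 1 without the 3 libraries, 2007 without the 2 WT isotype libraries, 4131 by voom and 1154 by DESeq2; it was not run with only the 2 groups, since it needs all 4. Response similarity was 0.147 without a filter (0.54), where near-zero genes enter.

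The labels do not say whether numbers pair the samples. With the group means removed, 30 pairs of the same title number correlated at a mean of -0.001, 9 of them over 0.1. For single pairs of arms this mean ran from -0.286 (WT isotype and B-depleted isotype) to 0.213 (WT and B-depleted combination). Of 21 samples 4 correlated best with their own number. These values give no sign of pairing over all arms but cannot exclude it. A replicate block by title number gave 33 genes in B-depleted tumours, 1 in the isotype comparison and 0 for the interaction, and 12 isotype lists (7); the replicate block by description code gave 14 and 1 in the first 2.

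Lists past the threshold with an estimated correlation were 0 in WT (20), 0 in B-depleted (10), 1 in isotype (7), 0 under the combination (19) and 0 for the interaction (20); fry passed 4 in B-depleted, 0 in isotype and 0 for the interaction. The covariate left 12 in WT and 13 for the interaction, and 18 isotype lists passed without the 3 B-depleted libraries.

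Leaving out 1 library gave 11 to 176 genes in B-depleted tumours, 0 to 2 in isotype, 2182 to 7606 under the combination and 0 to 1540 for the interaction, and 5 to 14 isotype lists (11, 13 and 14 without WT_isotype replicate 3, Bdep_isotype replicate 5 and 6). The count in B-depleted tumours moved by over 1.5 times without WT_isotype replicate 1 (43) or 5 (36), WT_combo replicate 2 (40), Bdep_isotype replicate 1 (17), 2 (11), 3 (176), 4 (43), 5 (163) or 6 (27), or Bdep_combo replicate 1 (30), 3 (38) or 5 (18); in isotype without WT_isotype replicate 1 (2) or 2 (1); and under the combination without WT_combo replicate 4 (2182) or 5 (2251) or Bdep_combo replicate 1 (3635), 3 (3042) or 4 (3336). For the interaction the counts were 0 without WT_isotype replicate 2, 4 or 5, Bdep_isotype replicate 2 or 5 or Bdep_combo replicate 4, 1 without WT_combo replicate 4 or 5, Bdep_isotype replicate 3 or Bdep_combo replicate 2, 2 without WT_isotype replicate 3 or WT_combo replicate 2, 3 and 8 without Bdep_combo and Bdep_isotype replicate 1, 361 and 1540 without WT_combo replicate 1 and 3, and 1382 without Bdep_combo replicate 5. No single library moved the WT count (7691 to 10240), the lists past the threshold in WT (19 to 21), in B-depleted tumours (9 to 15), under the combination (18 to 19) or for the interaction (18 to 21), the list scores past it in WT (13 to 18, against 15) or those under the combination (13 to 17, against 15) by over 1.5 times. Response similarity then ran from 0.336 to 0.635. Cfd ran from -0.76 to 6.15 and Cyp2e1 from -0.93 to 5.37 under the combination, both reversed without Bdep_combo replicate 4.

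The covariate reversed these WT changes: Pvalb (-0.076), Angptl1 (-0.63), Cd79b (-0.62), Ighd (-0.91), Ikzf4 (-0.35), Siglech (-2.35), Postn (-0.16), Eng (-0.42), Cldn5 (-0.18), Pfkfb3 (-0.16), Tnnt3 (-0.77), Ms4a1 (-1.50), Cd79a (-0.61), Cd4 (-0.17), Bub1 (0.029), Hk2 (0.042), Ldha (0.29), Ndrg1 (0.20) and Alb (0.35). Among list medians it reversed, in WT, B cells (-0.62), regulatory T cells (-0.35), macrophages (-0.22), dendritic cells (-0.58), fibroblasts (-0.87), endothelium (-0.80), cell cycle (0.16) and hypoxia (0.20); in B-depleted tumours fibroblasts (-0.19) and, by test direction, class II (0.078); under the combination fibroblasts (0.35) and endothelium (0.25); and for the interaction B cells (0.32), plasma cells (0.32), macrophages (0.43), fibroblasts (0.64) and endothelium (0.34). The Y-linked level differs between the arms, so this covariate takes up part of any arm difference by construction. With 12.45 M counts on average in B-depleted combination libraries, depth limits genes near 1 CPM there most.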
